A study of Mus musculus with 29 samples.

How the data were processed

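RNA-seq was used to measure transcripts in 26 libraries of mouse E14 embryonic stem cells made from total RNA extracted with Trizol, per the labels' protocols. Samples were grouped by their titles. The authors deposited raw counts of reads per gene for each library, whole numbers that were not normalised, followed by 5 closing totals of reads given to no gene. The submitters' processing notes name HISAT2 2.1.0, HTSeq 0.9.1, DESeq2 1.18.1, Bowtie2 2.3.1 and the mm10 build, without saying which step each was used for. The gene annotation and the strand setting of the counting are not given in the sources used here, so overlapping and antisense genes of the HOXA region (Hotairm1, Hoxaas2, Hoxaas3) are uncertain, as are near-identical gene copies such as the Zscan4, Usp17l, Tcstv and Pramef families. The 3 chromosome conformation (Capture-C) samples of the series were not analysed here.

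Library totals over genes were 7107938 to 9802499 counts. The closing totals were kept out of library sizes and tests. Of all reads in the files, 35.6% to 41.5% fell in no gene, 16.7% to 20.8% aligned to several places, 0.865% to 1.52% were ambiguous between genes, 3.15% to 5.79% were of low quality and 1.54% to 3.32% were not aligned. Such depth leaves few counts for genes of a few CPM, and intervals and floors cover counting error only. Where every library of a group had no count, a fold is given as a lower bound against a floor of 3 counts over the group. The files of the first arm name 52535 genes, 48108 of which matched a symbol in the reference table, and those of the enhancer arm 52636 gene IDs, 52403 of which matched. Coordinates come from a RefSeq table of GRCm38.p6, the assembly behind mm10.

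Each arm was fitted on its own because it has its own wild type: 18 libraries in one fit and 8 in the other, so that all groups of an arm share one estimate of the spread. Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, after TMM scaling (factors 0.696 to 1.15) and the filterByExpr filter with a minimum count of 10 and a minimum total of 15, which left 16979 and 16653 genes. The Benjamini-Hochberg method was applied over all genes tested, with a threshold of 0.05. Common dispersions were 0.00758 and 0.00298. The comparisons were RA (mean of both wild types after RA minus WT-RA-0d), each knockout minus the wild type that its title names, DKO minus Hoxa1-WT (no title names a wild type for it), the direct contrasts between knockouts, the difference between the wild types, and the difference of the Halr1-KO and Hoxa1-KO effects and of Halr1 loss with and without the Hoxa1 knockout. Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset inter-gene correlation of 0.01 and adjustment over the lists of a comparison. Counts of list members are given over all genes tested and adjusted over the list alone. The HOXA list holds Hoxa1 and the list of noncoding RNAs and neighbours holds Halr1, so a targeted gene counts in those tests.

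The groups, tests, 20 gene lists, alternatives and rule for named genes were fixed before the data were examined. The lists cover the HOXA genes, noncoding RNAs and neighbours of the HOXA locus, the HOXB, HOXC and HOXD genes, retinoid signalling, naive, core and formative pluripotency, neural, mesendoderm, extra-embryonic endoderm, trophectoderm, the 2-cell-like state, fibroblasts and feeder cells, Wnt, ERK, LIF and STAT3, p53, stress and heat shock, proliferation and the mitochondrial genome. The rule names Halr1 and the HOXA genes in each comparison, the 10 genes with the largest change in each direction with a mean of at least 5 CPM and no overlap between groups (which chance gives to 10% of genes with 3 libraries against 3, and to a larger share, 2 of the 6 orderings, with 2 against 2), and up to 4 members of each list with the smallest p. Some genes were named outside that rule after their values were seen, among them further list members, Trp53 outside En1-KO, Y-linked genes, Ppp1ca and genes named for the contrasts between wild types or knockouts. RA-responsive lists hold 200 genes in each direction.

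Replicates were compared before use. Their counts differed by more than sampling noise in every pair (chi-square per gene 1.97 to 8.69), so no library was merged. WT-RA-0d replicate 1 stood apart from the other 2 of its group (8.31 and 8.69 against 1.97), and 12419 genes passed for RA without it. The series calls them biological replicates, but nothing says that they came from separate cultures or clones, so p-values measure only the spread between these samples, which may be technical. Alternatives were DESeq2 1.42.0, other scaling, no filter, a fit of the compared groups alone, other controls, a minimum change of 1 on the log2 scale, the replicate number as a block, leaving out each library and an estimated inter-gene correlation. Scaling by library totals alone was added after the scaling factors were seen, and Hoxa1-WT as a control for Halr1-KO after the levels in both wild types were seen.

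The procedure was tested on simulated data with 200 changed genes per comparison. For the 4 comparisons of the first arm with a control, it recovered 38.8% to 44.8% of genes changed by 0.5 on the log2 scale, 61.2% to 76.1% of those changed by 1 and 87.9% to 93.9% of those changed by 2, and 3.52% to 5.41% of its calls were false. For the enhancer arm it recovered 43.3% to 58.2%, 70.1% to 79.1% and 86.4% to 95.5%, and 5.88% (En2-KO), 10.8% (En1/2/3-KO) and 11.7% (En1-KO) of its calls were false.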

Results

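Transcripts were counted in mouse E14 embryonic stem cells, an XY line, before and after retinoic acid (RA) was used to start differentiation. The study asks what a long noncoding RNA (Halr1), a homeobox gene (Hoxa1) and enhancers near the HOXA cluster do for the genes induced by RA. Undifferentiated cells (WT-RA-0d) grew with leukaemia inhibitory factor (LIF) and inhibitors of MEK and GSK3, and the other cells were differentiated for 24 h with 2 µM RA after these were withdrawn. The first arm held 18 libraries, 3 each of WT-RA-0d, Halr1-WT, Halr1-KO, Hoxa1-WT, Hoxa1-KO and the double knockout of both genes (DKO). The enhancer arm held 8 libraries, 2 each of its own wild type (En-WT), En1-KO, En2-KO and En1/2/3-KO, all after RA. Each library held 7107938 to 9802499 gene counts. Levels are counts scaled to library size (CPM) given as mean ± SD, and log2 fold changes carry their SE. In the 7 comparisons of a condition with its control, the libraries of the groups compared did not overlap for any gene said to have changed, unless stated.

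After 24 h in RA the genes of the HOXA cluster rose from low levels, genes that bind and break down retinoids rose, and most genes of the naive stem cell state and of LIF signalling fell. Of these list calls, that of the retinoid genes alone held with an estimated correlation. Hoxa1, an early target of RA, rose from 4.39 ± 0.492 CPM (n = 3) in WT-RA-0d to 18.6 ± 1.41 in Halr1-WT and 69.0 ± 3.18 in Hoxa1-WT (n = 3 each), a log2 fold change of 3.03 ± 0.16 (edgeR adjusted p = 1.46e-16). Halr1 is a long noncoding RNA gene between Skap2 and Hoxa1. It rose from 10.2 ± 1.28 CPM to 203 ± 11.5 and 134 ± 12.2, by 4.02 ± 0.11 (edgeR adjusted p = 6.52e-23). Of the tested HOXA genes, all 8 rose, among them Hoxa5 by 5.99 ± 0.26, Hoxa3 by 5.14 ± 0.27 and Hoxa9 by 1.29 ± 0.35, whose groups overlapped. Cyp26a1, the enzyme that degrades RA, rose from 0.210 CPM to 92.2 and 367 CPM. Stra8, Dhrs3 and Rbp1 rose by 5.35, 3.85 and 3.71 on the log2 scale. Hoxb2 had no count in WT-RA-0d and reached 7.88 ± 0.934 and 29.6 ± 2.25 CPM. The mean of both wild types (18.7 CPM) was 160-fold the floor of 3 counts over the group, which is a lower bound of the rise.

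The HOXA list passed the list test (median log2 fold change 4.15, camera adjusted p = 0.00101), a call lost with an estimated correlation (adjusted p = 0.062). In the retinoid signalling list, 20 of 25 genes rose and 4 fell (median 2.11, camera adjusted p = 0.000183), a call that held with an estimated correlation (adjusted p = 0.00967). Among the other HOX clusters, 11 of 23 genes rose and 4 fell (median 1.05, also with genes at 0 set to their bounds; camera adjusted p = 0.0156, and adjusted p = 0.062 with an estimated correlation). Of the naive pluripotency genes, 14 of 21 fell and 6 rose (median -0.77, camera adjusted p = 0.0244, and adjusted p = 0.062 with an estimated correlation). Klf4 fell from 533 ± 45.2 CPM to 31.9 ± 3.33 and 59.3 ± 0.559, and Tfcp2l1 by 2.86 ± 0.05 on the log2 scale. Of the LIF and STAT3 targets, 9 of 11 fell and 1 rose (median -1.66, camera adjusted p = 0.00309, and adjusted p = 0.0808 with an estimated correlation). They include the receptor genes Lifr (log2 fold change -2.83) and Il6st (-2.63). In the formative and primed list, 9 of 15 rose and 3 fell (median 0.88, camera adjusted p = 0.0388, and adjusted p = 0.208 with an estimated correlation), led by Sox3 at 3.40 and Dnmt3a at 2.095. All 14 transcripts of the mitochondrial genome fell (median -1.55, camera adjusted p = 0.000268, and adjusted p = 0.208 with an estimated correlation).

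The other 13 lists did not pass. Members that rose and fell numbered 4 and 6 of 11 for the noncoding RNAs and neighbours of HOXA, 6 and 6 of 12 for core pluripotency, 6 and 4 of 17 for neural genes and 3 and 6 of 10 for mesendoderm. They numbered 15 and 5 of 21 for extra-embryonic endoderm, where Gata6 rose by 4.74 ± 0.27 and Lama1 fell by 3.11 ± 0.07 on the log2 scale. For trophectoderm they were 7 and 5 of 12, for the 2-cell-like state 7 and 0 of 12, and for fibroblasts and feeder cells 2 and 3 of 6. For Wnt targets they were 4 and 8 of 14, with Axin2 at -3.07 and Sp5 at -6.46, and for ERK targets 9 and 5 of 17. The p53 targets gave 4 and 12 of 18, the stress and heat shock list 8 and 5 of 15 and proliferation 8 and 7 of 19. Adjusted over the list alone, the counts were the same in all 20 lists except the neural one, with 5 and 4. Median, mean and test differed in sign for the core, neural, HOXA neighbour and fibroblast lists.

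Over all genes, 13005 of 16979 differed after RA (6491 higher, 6514 lower, edgeR at the 0.05 threshold), with H19 rising from 0.0364 CPM to 28.7 and 100.0 CPM and Nkx1-2 falling by 5.74 ± 0.25 on the log2 scale. The Y-linked Ddx3y and Eif2s3y stood at 40.2 ± 5.29 and 29.4 ± 8.37 CPM in WT-RA-0d and had no count in any Halr1-WT or Hoxa1-WT library, so the untreated and treated lines also differed in Y-linked transcripts. Scaling by library totals alone moved the median of all genes by -0.12. RA was added as LIF and the inhibitors were withdrawn, so the comparison covers both, and the 2 wild-type groups after RA differed from each other as given later.

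In the Halr1 knockout the targeted RNA was lower but still present: Halr1 stood at 82.1 ± 7.78 CPM in Halr1-KO and 203 ± 11.5 in Halr1-WT (n = 3 each; log2 fold change -1.30 ± 0.09, edgeR adjusted p = 2.08e-12). Halr1 was at 92.5 ± 12.4 CPM in Hoxa1-KO, where it was not targeted, near its level in Halr1-KO. Against Halr1-WT the HOXA genes were higher and the naive pluripotency genes lower. Hoxa1 rose by 1.13 ± 0.14 on the log2 scale (40.6 ± 7.61 against 18.6 ± 1.41 CPM, edgeR adjusted p = 8.52e-08), Hoxa4 by 3.25 ± 0.20, Hoxa7 by 2.91 ± 0.18 and Hoxa5 by 2.24 ± 0.15. Nanog, a core factor of the naive state, was at 129 ± 2.91 CPM against 979 ± 8.87, a log2 fold change of -2.92 ± 0.06. Genes of extra-embryonic endoderm were higher, with Gata6 at 47.9 ± 7.04 against 3.94 ± 0.269 CPM and Sox17 up by 4.34 ± 0.39.

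Of the 8 HOXA genes 7 rose, and 8 adjusted over the list alone (median 2.05, camera adjusted p = 0.000535, and adjusted p = 0.0479 with an estimated correlation); Hoxa10 had a log2 fold change of 0.74 ± 0.34 (edgeR adjusted p = 0.0611). Of the naive pluripotency genes 17 of 21 fell and 3 rose (median -1.25, camera adjusted p = 8.57e-08), including Klf2 (-3.43), Prdm14 (-4.99) and Esrrb (-2.04). Of the extra-embryonic endoderm genes 16 of 21 rose and 2 fell (median 1.91, camera adjusted p = 2.38e-06), among them Lama1 (2.54) and Col4a2 (2.05), which encode parts of basement membrane. Retinoid genes rose in 14 of 25 and fell in 3 (median 0.60, camera adjusted p = 0.0224), with Cyp26b1 at 3.90 and the retinol transporter gene Stra6 at 2.101. The p53 targets fell in 15 of 18 and rose in 2 (median -0.63, camera adjusted p = 0.000526), with the pro-apoptotic Pmaip1 at -3.30. These counts were the same adjusted over the list alone except for HOXA, all 5 calls held with an estimated correlation, and the other 15 lists did not pass. Pgam2, a phosphoglycerate mutase gene, rose from 11.9 ± 1.42 to 1229 ± 73.5 CPM, and Magea8 fell by 7.35 ± 0.34 on the log2 scale. Magea8 was at 40.4 CPM in Halr1-WT, 0.230 in Halr1-KO and 0.135 in Hoxa1-WT, so its fall depended on the control (log2 fold change 0.73 against Hoxa1-WT).

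The control mattered for this comparison. Set against Hoxa1-WT, a control chosen after the levels in both wild types had been seen, the HOXA median was 0.33 (4 rose, 1 fell, camera adjusted p = 0.466) and Hoxa1 had a log2 fold change of -0.76. The extra-embryonic endoderm median was then 0.69 (camera adjusted p = 0.0384, and adjusted p = 0.127 with an estimated correlation) and the p53 target median -0.92 (camera adjusted p = 0.13). Retinoid genes then rose in 13 and fell in 9 (median 0.38, camera adjusted p = 0.417), and with the mean of both wild types they did not pass either (median 0.44, camera adjusted p = 0.115). With that mean control the HOXA (adjusted p = 0.166) and p53 (adjusted p = 0.0817) calls were lost with an estimated correlation, and the endoderm call held (adjusted p = 0.0174). Against Hoxa1-WT the naive pluripotency median was -1.07 (15 fell, 3 rose, camera adjusted p = 0.00203). Of the lists that passed only with another control, trophectoderm against Hoxa1-WT and the 2-cell-like state against Hoxa1-WT and the mean of both, none held with an estimated correlation. In all, 9602 of 16979 genes differed from Halr1-WT (4612 higher, 4990 lower, edgeR), or 2625 higher and 7538 lower scaled by library totals alone. That scaling moved the median of all genes by -0.33 on the log2 scale. Ribosomal protein genes took 20.8% of the counts in Halr1-KO and 16.0% in Halr1-WT, against 5.89% to 11.6% in the other groups. Ddx3y was at 11.5 ± 2.1 CPM in Halr1-KO and had no count in Halr1-WT.

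**Figure D1:**
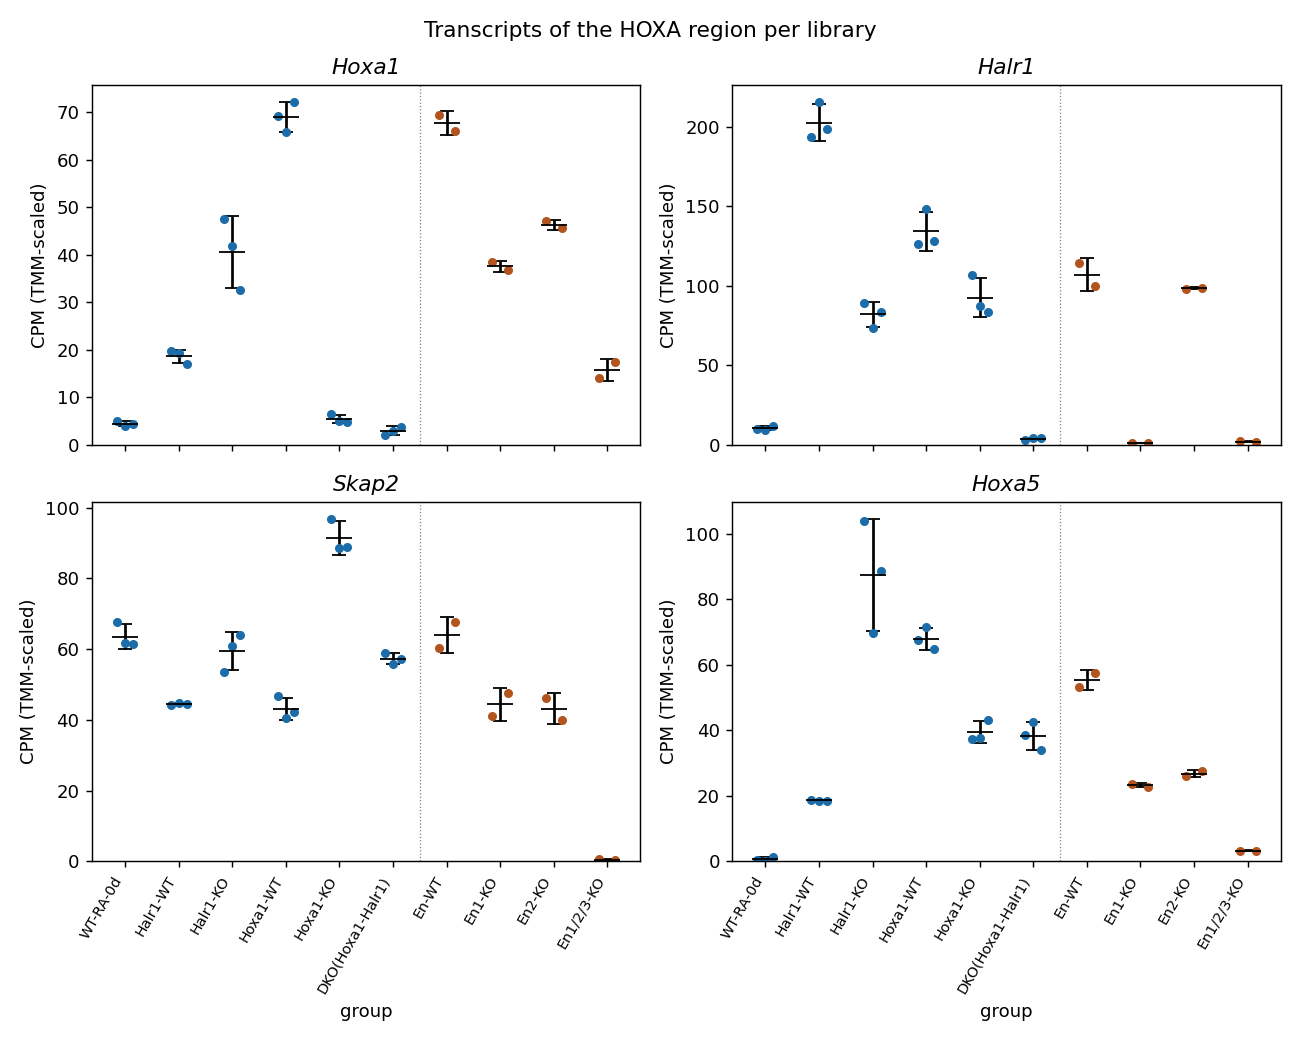
Hoxa1, Halr1, Skap2 and Hoxa5 in CPM (y axis) for each library (points) of the 10 groups (x axis), with the mean and SD as bars; the dotted line parts the first arm (3 libraries a group) from the enhancer arm (2 a group), which was scaled separately. Halr1 stood at 82.1 CPM in Halr1-KO, 3.76 in DKO and 0.916 in En1-KO, and Skap2 was near 0 only in En1/2/3-KO.

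In the Hoxa1 knockout, Hoxa1 itself was at 5.35 ± 0.877 CPM against 69.0 ± 3.18 in Hoxa1-WT (n = 3 each; log2 fold change -3.69 ± 0.15, edgeR adjusted p = 7.02e-17). The other HOXA genes that passed moved in both directions, some genes of other HOX clusters rose, and core pluripotency genes and transcripts of the 2-cell-like state fell. Halr1 fell by 0.54 ± 0.09 on the log2 scale (92.5 ± 12.4 against 134 ± 12.2 CPM, edgeR adjusted p = 2.3e-05), Hoxa5 by 0.78 ± 0.13 and Hoxa7 by 0.70 ± 0.16, while Hoxa9 rose by 1.182 ± 0.27. Hoxc9, at 0.135 ± 0.0569 CPM in the control, reached 4.17 ± 0.644, and Hoxc4 rose by 1.85 ± 0.21. The pluripotency genes Tdgf1, L1td1 and Sall4 fell by 1.29, 1.22 and 1.08 on the log2 scale, and Gata6 by 2.25 ± 0.15.

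Of the HOXA genes 1 rose and 3 fell, the targeted Hoxa1 among the latter, and the list did not pass (median -0.29, camera adjusted p = 0.232). Core pluripotency genes fell in 10 of 12 and rose in 1 (median -0.99, camera adjusted p = 4.67e-07), and the 2-cell-like genes fell in 8 of 12 (median -2.08, camera adjusted p = 0.00013). Proliferation genes fell in 10 of 19 and rose in 3 (median -0.16, camera adjusted p = 0.0123). These 3 calls held with an estimated correlation. The 2-cell-like list rests largely on near-identical Zscan4 copies, such as Zscan4a (-2.62) and Zscan4c (-2.33), whose counts are uncertain. A further 6 lists passed and were lost with an estimated correlation. HOXB, HOXC and HOXD genes rose in 14 of 23 and fell in 6 (median 1.90, camera adjusted p = 0.0257, then adjusted p = 0.0604 with an estimated correlation). Extra-embryonic endoderm fell in 14 of 21 and rose in 3 (median -0.68, camera adjusted p = 0.0123, then adjusted p = 0.0604 with an estimated correlation). Trophectoderm rose in 7 of 12 and fell in 1 (median 0.61, camera adjusted p = 0.0211, then adjusted p = 0.0604 with an estimated correlation). Formative genes fell in 9 of 15 and rose in 3 (median -0.62, camera adjusted p = 0.0193, then adjusted p = 0.163 with an estimated correlation). ERK targets fell in 9 of 17 and rose in 3, or 4 adjusted over the list alone (median -0.65, camera adjusted p = 0.0327, then adjusted p = 0.0632 with an estimated correlation), with Spry2 at -1.89 and Spry4 at -1.59. Mitochondrial transcripts fell in 9 of 14 (median -0.43, camera adjusted p = 0.00243, then adjusted p = 0.29 with an estimated correlation). Adjusted over the list alone, the other 8 passing lists gave the same counts.

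Several of these list results depended on the control. With the mean of both wild types, core pluripotency (10 of 12 lower, camera adjusted p = 9.21e-07) and the other HOX clusters (16 of 23 higher, 1 lower, camera adjusted p = 0.000754) passed and held with an estimated correlation. So did 3 lists that had not passed against Hoxa1-WT: naive pluripotency (14 of 21 lower, 1 higher, camera adjusted p = 5.36e-05), p53 targets (8 of 18 lower, camera adjusted p = 0.00397) and noncoding RNAs and neighbours of HOXA (9 of 11 higher, 1 lower, camera adjusted p = 0.00391). The 2-cell-like list (4 of 12 lower, camera adjusted p = 0.0638), proliferation (6 higher, 7 lower, median 0.02, camera adjusted p = 0.599) and extra-embryonic endoderm (4 higher, 5 lower, median 0.02, camera adjusted p = 0.844) then did not pass. Formative genes (camera adjusted p = 0.482), ERK targets (camera adjusted p = 0.433), trophectoderm (camera adjusted p = 0.433) and mitochondrial transcripts (camera adjusted p = 0.904) did not pass either.

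In all, 6437 of 16979 genes differed (3336 higher, 3101 lower, edgeR). Among the most raised was Asz1, up from 0.201 to 19.3 CPM (log2 fold change 6.48 ± 0.45), a gene at 22.2 CPM in the other wild type, Halr1-WT. Scml2 rose by 5.13 ± 0.19, and the imprinted Phlda2 fell by 2.44 ± 0.12 on the log2 scale. With the mean of both wild types as control, Hoxa5, Hoxa7 and Hoxa4 had log2 fold changes of 0.15, 0.21 and 0.95, so the direction of the changes in Hoxa5 and Hoxa7 depended on the control. Hotairm1, which overlaps Hoxa1, fell by 2.22 ± 0.25, a value that is uncertain because the strand setting of the counting is not given in the sources used here.

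In the double knockout both targets were near the untreated level or below it: Halr1 stood at 3.76 ± 0.663 CPM and Hoxa1 at 2.90 ± 0.908, against 134 ± 12.2 and 69.0 ± 3.18 in Hoxa1-WT (n = 3 each; log2 fold changes -5.15 ± 0.14 and -4.57 ± 0.17, edgeR adjusted p = 1.55e-21 and 5.46e-18). Of the HOXA genes other than the targeted one, Hoxa9 and Hoxa10 fell most, at -3.18 ± 0.42 and -2.65 ± 0.38, then Hoxa7 at -1.183, Hoxa5 at -0.83 and Hoxa3 at -0.40. Hoxa4 (0.20 ± 0.16) and Hoxa2 (0.14 ± 0.25) did not pass. Naive pluripotency genes were lower, with Nanog at 273 ± 3.98 against 739 ± 16.8 CPM, and p53 targets were higher, with Mdm2 up by 0.97 ± 0.08 and Trp53inp1 by 1.28 ± 0.07. Sox3 rose by 2.46 ± 0.11, while the neural list went both ways and did not pass (3 of 17 rose, 4 fell, median -0.04, camera adjusted p = 0.751).

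Of the HOXA genes 6 of 8 fell, the targeted Hoxa1 among them (median -1.005, camera adjusted p = 0.00191, and adjusted p = 0.0788 with an estimated correlation). This depended on the control, which the labels do not name for the double knockout: against Halr1-WT 5 rose and 3 fell (median 0.64, camera adjusted p = 0.738), and against the mean of both 2 rose and 3 fell (median -0.08, camera adjusted p = 0.452). Naive genes fell in 13 of 21 and rose in 2 (median -0.74, camera adjusted p = 3.26e-07). Core pluripotency genes fell in 8 of 12, or 9 adjusted over the list alone (median -0.47, camera adjusted p = 1.97e-05). The p53 targets rose in 13 of 18, or 15 with 1 falling adjusted over the list alone (median 0.45, camera adjusted p = 5.6e-08). These 3 calls held with an estimated correlation. Against Halr1-WT the naive call held with an estimated correlation too, while the core list (4 rose, 8 fell, camera adjusted p = 0.152) and the p53 list (9 rose, 5 fell, median 0.32, camera adjusted p = 0.253) did not pass. Against the mean of both wild types the naive call held, and core (adjusted p = 0.0512 with an estimated correlation) and p53 (adjusted p = 0.0558 with an estimated correlation) were lost. Extra-embryonic endoderm fell in 9 of 21, or 10 adjusted over the list alone, and rose in 1 (median -0.28, camera adjusted p = 0.0364, and adjusted p = 0.122 with an estimated correlation). The stress list fell in 7 of 15 and rose in 1, or 2 adjusted over the list alone (median -0.25, camera adjusted p = 0.00961, and adjusted p = 0.0823 with an estimated correlation), with Atf4 at -1.31 and Chac1 at -1.59. The endoderm list did not pass against Halr1-WT (median 0.38, camera adjusted p = 0.314) or the mean of both (median 0.25, camera adjusted p = 0.84). The retinoid, formative, 2-cell-like and mitochondrial lists were higher and passed with either of these controls, and none held with an estimated correlation. In all, 5427 genes differed from Hoxa1-WT (2657 higher, 2770 lower, edgeR), or 10405 with Halr1-WT as control and 8344 with the mean of both. Ddx3y stood at 23.2 ± 2.00 CPM in the double knockout and had no count in Hoxa1-WT.

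Direct contrasts between knockouts need no wild type, but the lines compared may differ beyond the targeted genes. Ddx3y stood at 23.2 CPM in DKO and had no count in Hoxa1-KO, so DKO minus Hoxa1-KO does not isolate the loss of Halr1. With Hoxa1 low in both (5.35 CPM in Hoxa1-KO and 2.90 in DKO), DKO had less Halr1 than Hoxa1-KO (log2 difference -4.62), and Hoxa9 and Hoxa10 were lower (-4.36 and -3.01), while Hoxa5 did not differ beyond the spread (-0.04, edgeR adjusted p = 0.819). The HOXA list did not pass there (5 of 8 lower, and 2 higher adjusted over the list alone, camera adjusted p = 0.076). HOXB, HOXC and HOXD genes were lower in 13 of 23, or 14 adjusted over the list alone, and higher in 2 (median -1.82, camera adjusted p = 0.000509). The p53 targets were higher in 13 of 18 and lower in 1 (median 0.84, camera adjusted p = 4.67e-07). Trp53 itself stood at 360 CPM in DKO and 104 in Hoxa1-KO. Naive genes were lower in 13 of 21 and higher in 3 (camera adjusted p = 0.00307), noncoding RNAs and neighbours of HOXA lower in 6 of 11, or 7 adjusted over the list alone, the targeted Halr1 among them (camera adjusted p = 0.005), and 2-cell-like genes higher in 8 of 12 (camera adjusted p = 4.99e-05). These 5 calls held with an estimated correlation. A further 5 did not hold: formative pluripotency (9 of 15 higher, 3 lower, adjusted p = 0.0928 with an estimated correlation), core pluripotency (8 of 12 higher, 3 lower, adjusted p = 0.0552 with an estimated correlation), trophectoderm (6 of 12 lower, 2 higher, adjusted p = 0.0743 with an estimated correlation), the stress list (10 of 15 lower, 3 higher, adjusted p = 0.0959 with an estimated correlation) and mitochondrial transcripts (10 of 14 higher, adjusted p = 0.163 with an estimated correlation). Adjusted over the list alone, 11 formative, 9 core, 4 stress and 12 mitochondrial members were higher, and the other counts of these 5 lists were the same. Set against Halr1-KO, DKO had lower levels of all 8 HOXA genes, the targeted Hoxa1 among them (median -1.83, camera adjusted p = 0.0102, and adjusted p = 0.127 with an estimated correlation), with Hoxa1 at -3.81, Hoxa9 at -3.04 and Hoxa5 at -1.20. Halr1 differed as well, at 82.1 CPM in Halr1-KO and 3.76 in DKO, so DKO minus Halr1-KO does not isolate the loss of Hoxa1. There extra-embryonic endoderm was lower in 13 of 21 and higher in 1, the other HOX clusters lower in 12 of 23 (11 adjusted over the list alone) and higher in 1. The 2-cell-like genes (10 of 12) and p53 targets (13 of 18, or 14 adjusted over the list alone, with 3 lower) were higher, and these 4 calls were lost with an estimated correlation (adjusted p = 0.0715 for each). Mitochondrial transcripts, 12 of 14 higher and 1 lower, were lost too (adjusted p = 0.444 with an estimated correlation). DKO differed from Hoxa1-KO in 6977 genes (3359 higher, 3618 lower) and from Halr1-KO in 12034 (6344 higher, 5690 lower, or 9762 and 3109 scaled by library totals alone, which moved the median of all genes by 0.65).

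The wild-type groups after RA were themselves far apart. Halr1-WT had less Hoxa1 than Hoxa1-WT (log2 difference -1.89), less Hoxa4 (-2.23), Hoxa5 (-1.87), Hoxa3 (-1.79), Gata6 (-2.90) and Sox17 (-2.49), and more Halr1 (0.59) and Nanog (0.41). Of the HOXA genes 7 of 8 were lower (median -1.80, camera adjusted p = 0.00544, and adjusted p = 0.165 with an estimated correlation), and extra-embryonic endoderm genes were lower in 13 of 21 and higher in 3, or 5 adjusted over the list alone (median -1.06, camera adjusted p = 0.037, and adjusted p = 0.165 with an estimated correlation). The 2-cell-like genes were lower in 9 of 12 (median -1.91, camera adjusted p = 0.00317, and adjusted p = 0.162 with an estimated correlation). Mitochondrial transcripts were lower in 11 of 14 and higher in 1 (median -0.88, camera adjusted p = 0.00317, and adjusted p = 0.295 with an estimated correlation). In all, 9968 genes differed between them (4930 higher in Halr1-WT, 5038 lower, edgeR), or 3005 and 7807 scaled by library totals alone, which moved the median by -0.34. No batch label was given for either group, so a batch and the group cannot be told apart.

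**Figure D2:**
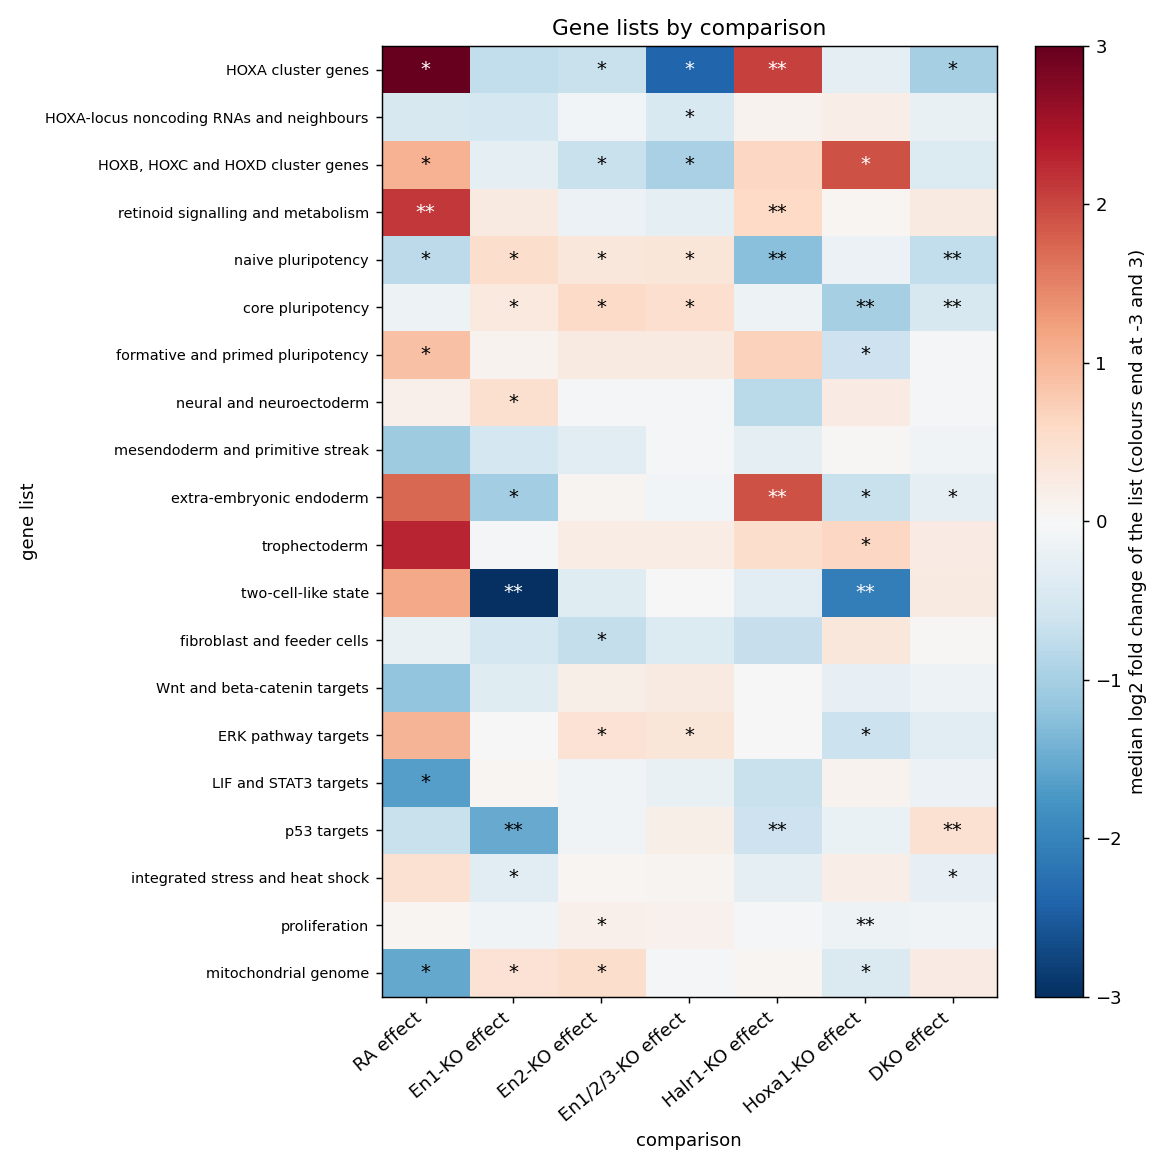
Median log2 fold change (colour, from -3 to 3) of 20 gene lists (y axis) in the 7 comparisons of a condition with its control (x axis). A single star marks a camera adjusted p under 0.05 with the preset correlation, and a double star one that also held with an estimated correlation; HOXA genes had medians of 4.15 after RA and -2.39 in En1/2/3-KO.

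In the enhancer arm the knockouts removed DNA elements, so no transcript checks their labels directly. In En1-KO there was almost no Halr1, 0.916 ± 0.113 against 107 ± 10.3 CPM in En-WT (n = 2 each, log2 fold change -6.86 ± 0.16, edgeR adjusted p = 2.36e-22). Hoxa1 was at 37.6 ± 1.16 CPM in En1-KO against 67.7 ± 2.45 (-0.85 ± 0.09, edgeR adjusted p = 7.85e-09). Hoxa5 fell by 1.25 ± 0.11 on the log2 scale, Hoxa4 by 0.76 ± 0.22, Hoxa7 by 0.71 ± 0.22 and Hoxa3 by 0.40 ± 0.16. Trp53, the gene of the p53 tumour suppressor on chromosome 11, was at 4.26 ± 0.922 CPM in En1-KO against 332 ± 9.03 in En-WT (-6.26 ± 0.09). Targets of p53 fell with it, including Eda2r (-8.83), Ccng1 (-3.57) and Phlda3 (-3.18). Transcripts of the 2-cell-like state fell as well, with Zscan4e at -5.00 and Zscan4a at -4.41, and Gata6 fell by 3.34 ± 0.13. Such low levels were not particular to En1-KO, though the arms were scaled separately. Gata6 stood at 5.14 CPM in En1-KO, 6.22 in Hoxa1-KO and 3.94 in the wild type Halr1-WT, and between 22.5 and 64.0 in the other groups after RA. Zscan4c stood at 1.7 CPM in En1-KO, 2.6 in Hoxa1-KO, 4.1 in Halr1-WT and 3.7 in Halr1-KO.

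Of the p53 targets 13 of 17 fell and 2 rose in En1-KO (median -1.52, camera adjusted p = 1.75e-06). Of the 2-cell-like genes, many of them near-identical copies with uncertain counts, 12 of 14 fell (median -3.07, camera adjusted p = 8.52e-08). These 2 calls held with an estimated correlation (adjusted p = 0.049 for each). The HOXA list, with 5 of 8 lower, did not pass (median -0.74, camera adjusted p = 0.0796). Naive genes rose in 16 of 21 and fell in 3 (median 0.53, camera adjusted p = 8.43e-05, and adjusted p = 0.0614 with an estimated correlation), with Klf2 at 1.46 and Tcl1 at 1.75. Extra-embryonic endoderm fell in 14 of 20 and rose in 2 (median -1.05, camera adjusted p = 7.04e-05, and adjusted p = 0.0621 with an estimated correlation). Core pluripotency rose in 6 of 12 and fell in 1 (camera adjusted p = 0.0388, and adjusted p = 0.2 with an estimated correlation). Neural genes rose in 6 of 17 and fell in 1 (camera adjusted p = 0.0472, and adjusted p = 0.266 with an estimated correlation). The stress list fell in 10 of 15 and rose in 3 (camera adjusted p = 0.0278, and adjusted p = 0.18 with an estimated correlation). Mitochondrial transcripts rose in 10 of 14 and fell in 2 (camera adjusted p = 0.0313, and adjusted p = 0.728 with an estimated correlation). Adjusted over the list alone, the counts of these 9 lists were the same. The Y-linked Ddx3y stood at 0.314 ± 0.444 CPM in En1-KO and 25.2 ± 0.137 in En-WT. In all, 8609 of 16653 genes differed (4356 higher, 4253 lower, edgeR), or 3067 and 5967 scaled by library totals alone, which moved the median by -0.16. On simulated data 11.7% of the calls of this comparison were false, above the nominal share.

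**Figure D3:**
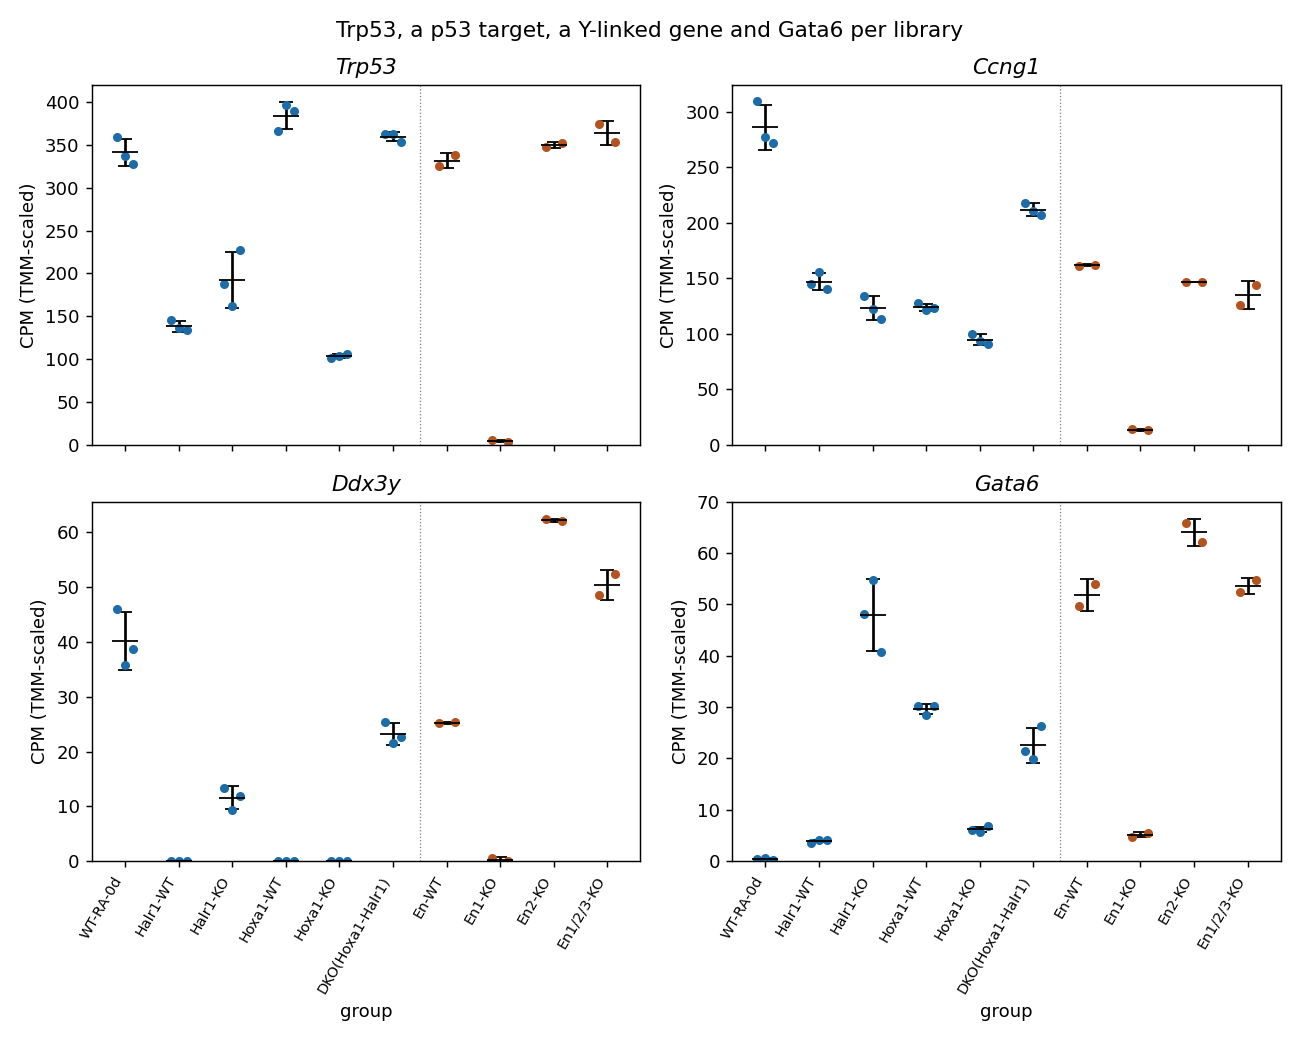
Trp53, its target Ccng1, the Y-linked Ddx3y and the endoderm gene Gata6 in CPM (y axis) for each library (points) of the 10 groups (x axis), with the mean and SD as bars; the dotted line parts the separately scaled arms. Trp53 stood at 4.26 CPM in En1-KO and between 104 and 385 CPM in the other groups, and Ddx3y had no count in Halr1-WT, Hoxa1-WT or Hoxa1-KO.

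Several HOXA genes were lower in En2-KO, without a detected change in Halr1, which was at 98.4 ± 0.621 against 107 ± 10.3 CPM (log2 fold change -0.12 ± 0.08, edgeR adjusted p = 0.243). Hoxa1 fell by 0.55 ± 0.09 on the log2 scale (46.3 ± 1.04 against 67.7 ± 2.45 CPM, n = 2 each, edgeR adjusted p = 1.71e-05), Hoxa4 by 1.14 ± 0.23, Hoxa5 by 1.05 ± 0.11, Hoxa7 by 0.80 ± 0.22 and Hoxa9 by 1.30 ± 0.49. The fall of Hoxa9 rests on low and uneven levels, 1.56 ± 1.57 CPM in En2-KO against 3.845 ± 0.418 in En-WT. Core pluripotency genes rose, led by Utf1 (1.26 ± 0.04) and L1td1 (0.98 ± 0.04), and so did 10 of 17 ERK targets, such as Spry4 (1.10) and Myc (1.36), but both list calls were lost with an estimated correlation. The cell cycle genes Cdkn1c, an inhibitor, and Ccnd2, a cyclin, fell by 1.97 and 2.09.

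Of the HOXA genes 5 of 8 fell, or 6 adjusted over the list alone (median -0.68, camera adjusted p = 0.0112). Of the HOXB, HOXC and HOXD genes 11 of 21 fell (median -0.67, camera adjusted p = 0.000168). Each of these lists had adjusted p = 0.146 with an estimated correlation. Their medians were alike, so a fall particular to the HOXA locus is not shown for En2-KO. All 12 core pluripotency genes rose (median 0.58, camera adjusted p = 8.82e-08, and adjusted p = 0.0694 with an estimated correlation). Naive genes rose in 11 of 21 and fell in 3, or 4 adjusted over the list alone (median 0.33, camera adjusted p = 0.0131), and ERK targets rose in 10 of 17 and fell in 1 (median 0.43, camera adjusted p = 0.000611), each with adjusted p = 0.146 with an estimated correlation. Mitochondrial transcripts rose in 12 of 14 (median 0.53, camera adjusted p = 7.17e-05, and adjusted p = 0.351 with an estimated correlation). Proliferation genes rose in 11 of 19 and fell in 3 (median 0.16, camera adjusted p = 0.014), and fibroblast genes fell in 3 of 6, or 4 adjusted over the list alone (median -0.72, camera adjusted p = 0.0131), each with adjusted p = 0.201 with an estimated correlation. In all, 5266 genes differed (2924 higher, 2342 lower, edgeR), or 3491 with DESeq2. Scaled by library totals alone they were 1614 and 4432, which moved the median by -0.16, as much as the whole proliferation median.

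In the triple deletion, En1/2/3-KO, every tested HOXA gene was lower, and by more than in either single deletion for most. Hoxa1 stood at 15.7 ± 2.27 CPM against 67.7 ± 2.45 in En-WT (n = 2 each; log2 fold change -2.11 ± 0.11, edgeR adjusted p = 4.93e-15), Hoxa5 fell by 4.08 ± 0.16 on the log2 scale, Hoxa7 by 2.98 ± 0.31 and Hoxa10 by 1.73 ± 0.44. Halr1 was at 1.94 ± 0.549 CPM (-5.78 ± 0.15). Skap2, the protein-coding neighbour on the far side of Halr1, fell from 64.0 ± 5.15 to 0.482 ± 0.284 CPM (-7.00 ± 0.23). On chromosome 6 of GRCm38, Skap2 lies at 51859165 to 52012549, Halr1 at 52102949 to 52113684 and Hoxa1 at 52155367 to 52160007, while positions of the enhancers are not given in the sources used here. Of the pluripotency genes, 13 of 21 naive and 8 of 12 core ones rose, with Nanog up by 0.92 ± 0.04, Pou5f1 by 0.79 ± 0.03 and Utf1 by 1.56 ± 0.04, but both list calls were lost with an estimated correlation.

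All 8 HOXA genes fell (median -2.39), as did 11 of 21 HOXB, HOXC and HOXD genes, or 14 adjusted over the list alone (median -0.98), each with camera adjusted p = 4.83e-06 and adjusted p = 0.0802 with an estimated correlation. Of the noncoding RNAs and neighbours of the locus 6 of 12 fell (median -0.46, camera adjusted p = 0.000803). Naive genes rose in 13 of 21 and fell in 4 (median 0.37, camera adjusted p = 0.00173) and ERK targets rose in 9 of 17 and fell in 1 (median 0.37, camera adjusted p = 0.00335). These 3 had adjusted p = 0.0909 with an estimated correlation. Core pluripotency rose in 8 of 12, or 9 adjusted over the list alone (median 0.51, camera adjusted p = 0.000231, and adjusted p = 0.0802 with an estimated correlation). In all, 6616 genes differed from En-WT (3573 higher, 3043 lower, edgeR), or 1990 and 5329 scaled by library totals alone, which moved the median by -0.20. Of the simulated calls of this comparison 10.8% were false, a share that need not hold for the real calls.

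Set against the single deletions directly, the triple deletion had lower Hoxa1 than En1-KO (log2 difference -1.26) and En2-KO (-1.56), lower Hoxa5 (-2.83 and -3.03) and lower Skap2 (-6.47 and -6.43). Halr1 was lower than in En2-KO (-5.65). It was higher than in En1-KO (1.08), but this rests on few counts, 28 over the En1/2/3-KO libraries and 16 over those of En1-KO. The HOXA genes were lower than in En1-KO in 7 of 8, or 8 adjusted over the list alone (median -1.92, camera adjusted p = 4.16e-05, and adjusted p = 0.0632 with an estimated correlation). They were lower than in En2-KO in 6 of 8, or 7 adjusted over the list alone (median -1.75, camera adjusted p = 1.76e-09, and adjusted p = 0.0545 with an estimated correlation). Trp53 was higher in the triple deletion than in En1-KO (6.39), as were p53 targets (15 of 17 higher, 1 lower, camera adjusted p = 1.19e-09) and all 14 of the 2-cell-like genes (camera adjusted p = 8.85e-11), and both list calls held with an estimated correlation. Other lists that passed against En1-KO were lost: the other HOX clusters (11 of 21 lower, or 12 adjusted over the list alone, adjusted p = 0.0861 with an estimated correlation), extra-embryonic endoderm (14 of 20 higher, 3 lower, or 4 adjusted over the list alone, adjusted p = 0.0752 with an estimated correlation), the stress list (8 of 15 higher, 2 lower, adjusted p = 0.0874 with an estimated correlation), proliferation (13 of 19 higher, 2 lower, adjusted p = 0.132 with an estimated correlation) and mitochondrial transcripts (11 of 14 lower, 2 higher, adjusted p = 0.408 with an estimated correlation). Against En2-KO the lists lost were noncoding RNAs and neighbours of HOXA (7 of 12 lower) and the 2-cell-like state (3 of 14 higher, or 4 adjusted over the list alone), each with adjusted p = 0.0697 with an estimated correlation. So were the other HOX clusters (3 of 21 lower, or 4 adjusted over the list alone, and 1 higher, adjusted p = 0.215 with an estimated correlation), naive pluripotency (6 of 21 higher, or 11 adjusted over the list alone, and 2 lower, adjusted p = 0.103 with an estimated correlation), extra-embryonic endoderm (2 of 20 lower, or 4 adjusted over the list alone, and 2 higher, adjusted p = 0.168 with an estimated correlation) and mitochondrial transcripts (12 of 14 lower, or 14 adjusted over the list alone, adjusted p = 0.187 with an estimated correlation). The triple deletion differed from En1-KO in 6462 genes (3381 higher, 3081 lower) and from En2-KO in 1736 (975 higher, 761 lower, or 720 and 1025 scaled by library totals alone). The count against En2-KO fell to 950 with DESeq2, and to 787, 845, 1004 and 1061 when En1/2/3-KO replicate 1 or 2, or En2-KO replicate 1 or 2, was left out.

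**Figure D4:**
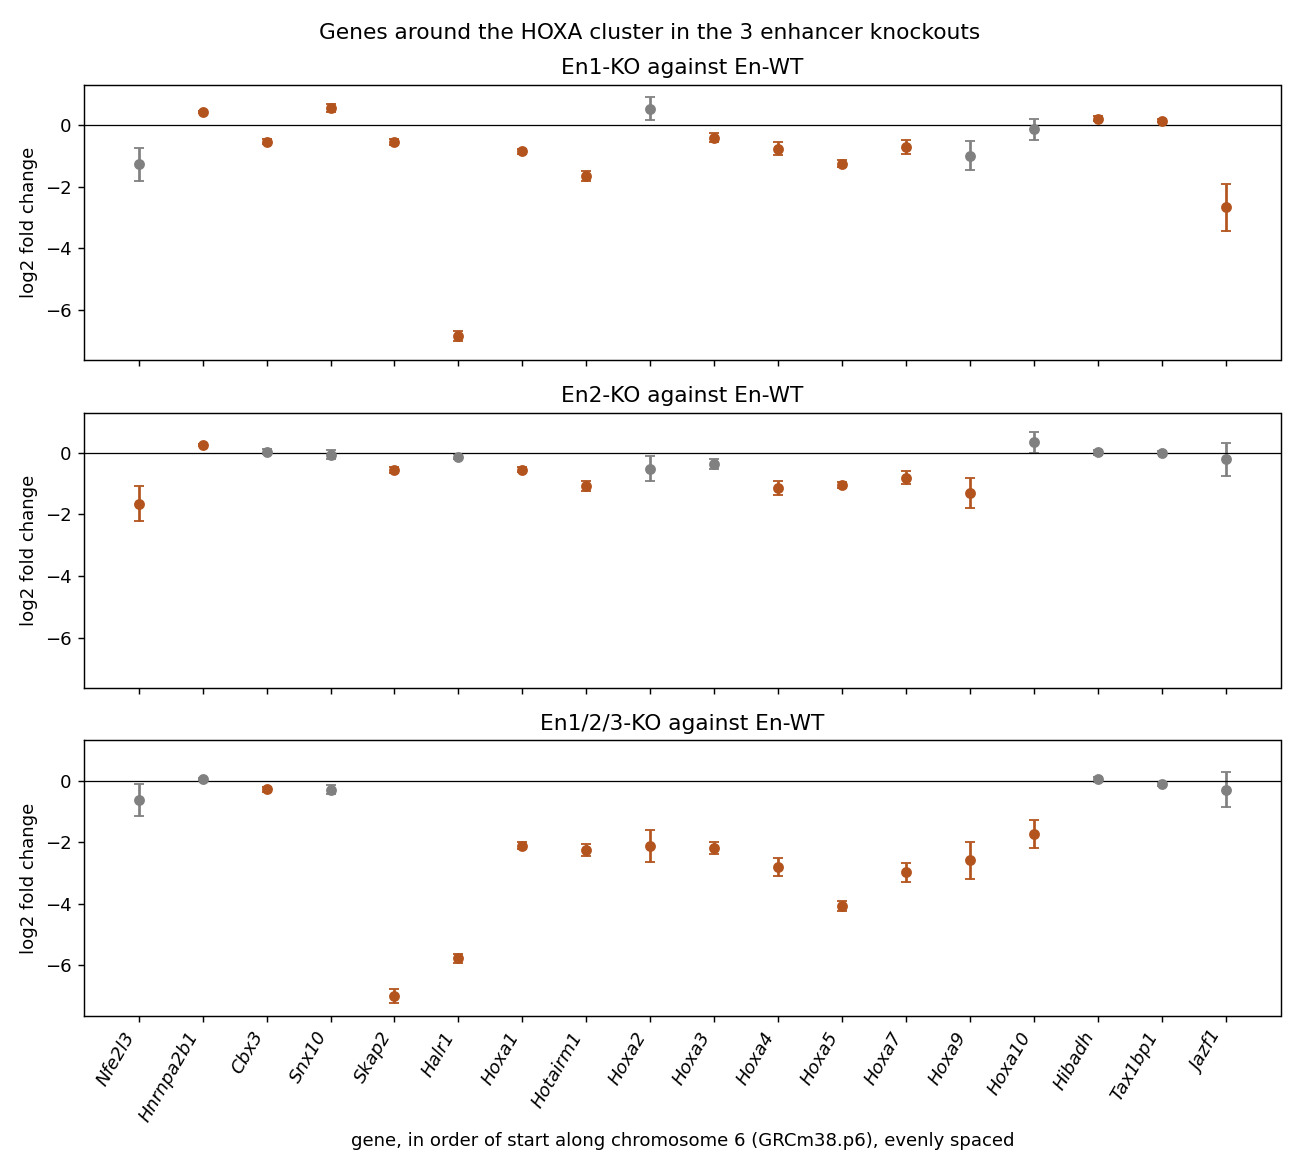
Log2 fold change (y axis, bars ± SE) of 18 genes around the HOXA cluster, in order of their start on chromosome 6 (x axis, evenly spaced), in each enhancer knockout (2 libraries a group). Orange points have an edgeR adjusted p under 0.05; Halr1 had values of -6.86 in En1-KO, -0.12 in En2-KO and -5.78 in En1/2/3-KO, and Skap2 of -7.00 in En1/2/3-KO.

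Genes that respond to RA were followed in each knockout, with the RA lists drawn from wild-type libraries that are not the knockout's control. Halr1-KO used Hoxa1-WT, Hoxa1-KO and DKO used Halr1-WT, and the enhancer knockouts used both. Halr1-WT and Hoxa1-WT differed in 9968 genes, so a list from either may also hold differences between lines. Of the 200 genes most clearly raised by RA, more were higher than lower in every enhancer knockout: 149 against 27 in En1-KO (median 0.57), 150 against 18 in En2-KO (0.38) and 165 against 21 in En1/2/3-KO (0.56). Of the 200 most clearly lowered by RA, 135, 108 and 158 were lower and 18, 13 and 8 higher. These 6 tests passed with the preset correlation and with an estimated one (adjusted p = 0.023 for each). The 3 knockouts share the same 2 En-WT libraries, so a low or high level in En-WT itself would move all of them, and their like directions are not independent. In Halr1-KO 114 of the raised genes were higher and 56 lower (median 0.33, camera adjusted p = 1.74e-05, and adjusted p = 0.105 with an estimated correlation). Of the lowered genes 125 were lower and 31 higher (median -0.49, camera adjusted p = 1.29e-08, and adjusted p = 0.0843 with an estimated correlation). In Hoxa1-KO the counts were 94 and 38 (median 0.16, camera adjusted p = 1.33e-05, and adjusted p = 0.386 with an estimated correlation) and 124 and 25 (median -0.30, camera adjusted p = 1.18e-11, and adjusted p = 0.105 with an estimated correlation). In DKO the raised genes did not pass (64 higher, 67 lower, camera adjusted p = 0.611), and of the lowered genes 68 were lower and 30 higher (median -0.05, camera adjusted p = 0.0329, and adjusted p = 0.607 with an estimated correlation).

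The calls of Halr1-KO and Hoxa1-KO, which have separate controls, overlapped in every direction. They shared 1117 higher genes against 906 for independent lists (odds ratio 1.46, Fisher's exact test, adjusted p = 8.6e-19) and 1068 lower genes against 911 (1.33, adjusted p = 3.1e-11). Genes of opposite direction also exceeded independence, with 988 against 842 (1.32, adjusted p = 1.88e-10) and 1120 against 980 (1.28, adjusted p = 4.77e-09). Among genes of at least 5 CPM the opposite pairs no longer did (odds ratios 1.00 and 1.01, adjusted p = 0.944 for each). Genes are not independent replicates, so these p-values describe genes, not cultures.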

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

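Tests chosen only after the result was seen are those of low depth and exchanged labels for the Y-linked genes, the 3 tests on Trp53 and the Hoxa1-WT control for extra-embryonic endoderm; the tests of missing Y transcripts, of composition and gene length for that list and the splits of the libraries were set before their results were seen, though the scaling that the composition test uses was added after the scaling factors were seen.

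The effects of the Halr1 knockout, which kept 82.1 of 203 CPM of Halr1, and of the Hoxa1 knockout differed by the test of the difference itself: 8595 genes passed (edgeR), 4054 higher and 4541 lower in the Halr1-KO effect, or 2490 and 6631 scaled by library totals alone. The difference was positive for the HOXA list, which holds the targeted Hoxa1 (median 2.73), retinoid signalling (0.53) and extra-embryonic endoderm (2.83), and negative for naive pluripotency (-0.92) and LIF and STAT3 targets (-0.48). By gene it was -0.76 for Halr1, 4.82 for Hoxa1, 2.43 for Hoxa2, 1.95 for Hoxa3, 3.41 for Hoxa4, 3.02 for Hoxa5 and 3.61 for Hoxa7. The calls for the naive and endoderm lists held with an estimated correlation, and those for HOXA (adjusted p = 0.0696), retinoid signalling (adjusted p = 0.081) and LIF and STAT3 (adjusted p = 0.144) were lost. Of 100 splits of these libraries drawn, only the real one, 1 of 100, called as many genes, and the highest other called 5746 (median of the others 0). The splits mix libraries of groups that lie far apart, which widens the spread. They show at most that the groups are not all alike, and do not test the difference of the effects.

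DKO minus Hoxa1-KO also differed from Halr1-KO minus Halr1-WT, the loss of Halr1 with and without the Hoxa1 knockout. Here 8562 genes passed (4379 higher, 4183 lower, or 6521 and 2667 scaled by library totals alone). List medians were -2.74 for HOXA, -1.05 for noncoding RNAs and neighbours of the locus (the targeted Halr1 among them), -1.58 for HOXB, HOXC and HOXD, 1.22 for naive pluripotency, -1.67 for extra-embryonic endoderm, 2.21 for the 2-cell-like state, 1.51 for p53 targets and 0.56 for mitochondrial transcripts, the last a call lost with an estimated correlation (adjusted p = 0.425). By gene the values were -3.31 for Halr1, -2.01 for Hoxa1, -1.47 for Hoxa2, -2.59 for Hoxa3, -2.89 for Hoxa4, -2.28 for Hoxa5, -3.39 for Hoxa7, -5.48 for Hoxa9 and -3.75 for Hoxa10. Of 100 splits drawn, only the real one called as many genes (1 of 100, highest other 7321, median of the others 0). Here too the splits mix groups that lie far apart, so they do not test the difference of the effects. Halr1 itself fell by unequal amounts, by 4.62 on the log2 scale in the first and 1.30 in the second, so the extent of Halr1 loss and the loss of Hoxa1 are not separated. Both sets of differences rest on the Halr1-WT libraries, which stood apart from Hoxa1-WT, and on lines that differ in Y-linked transcripts.

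For RA, 1 of 100 splits drawn, the real one, called 13005 genes, and the highest other called 9599 (median of the others 0). These splits too mix unlike groups, so they show at most that the groups are not all alike. For the 6 comparisons of 3 libraries with 3 the 10 splits are too few for a share under 0.05. The real split and the highest other called 9602 and 0 genes for Halr1-KO, 6437 and 1 for Hoxa1-KO, 5427 and 0 for DKO, 6977 and 1 for DKO minus Hoxa1-KO, 12034 and 0 for DKO minus Halr1-KO, and 9968 and 0 for the wild types.

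The Y-linked genes Eif2s3y, Uty and Ddx3y had 0 counts in Halr1-WT, Hoxa1-WT and Hoxa1-KO and 14, 2 and 6 in En1-KO. Low depth is argued against, since at the WT-RA-0d level the 4 Y-linked genes of at least 5 CPM would give at least 740 counts in each of those libraries. An exchange of the Halr1-WT and Halr1-KO labels predicted more Halr1 in Halr1-KO, and it was lower there by a log2 fold change of -1.30. But Halr1 stood at 82.1 CPM in Halr1-KO and 92.5 in Hoxa1-KO, where it was not targeted, against 203 in Halr1-WT and 134 in Hoxa1-WT. Its level thus varied between lines by nearly as much without a knockout of Halr1, so this test cannot decide. Cells without any Y transcript, as the prediction was written, are argued against by Mid1-ps1, with 310 counts in Hoxa1-WT, but this is a pseudogene whose reads may come from copies elsewhere, so a loss of the Y chromosome in these lines stays open. Halr1-KO had 206, 44 and 200 counts of Eif2s3y, Uty and Ddx3y, and DKO had 1477, 223 and 650. Their controls had 0, so each of these knockouts differed from its control in Y-linked transcripts as well as in the targeted genes. Whether the lines stem from different clones was not tested.

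Trp53 was at 4.26 CPM in En1-KO, with 13 of 17 p53 targets lower. The deletion of En1 as the cause is argued against by En1/2/3-KO, where Trp53 had a log2 fold change of 0.13, provided both deletions remove the same element. Loss of Halr1 is argued against by the same libraries, where Halr1 was at 1.94 CPM. The test written for loss of Halr1 used DKO, where Trp53 had a log2 fold change of -0.10. DKO also lacks Hoxa1, and Trp53 stood at 104 CPM in Hoxa1-KO, so DKO does not isolate the loss of Halr1. With library totals alone Trp53 fell by 6.42 on the log2 scale. That scaling moved the median of all genes by -0.16, away from the limit set, so this test could not have found composition to be the cause. A candidate explanation that stays open and untested is a property of the En1-KO clone outside the HOXA locus. Changes in En1-KO away from the locus, such as those of p53 targets, therefore cannot be assigned to the enhancer from these libraries.

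Extra-embryonic endoderm genes were higher in Halr1-KO than in Halr1-WT (median 1.91). With library totals alone the median was 1.58. That scaling moved the median of all genes by only -0.33, so it could not bring the list under 0.5. It shows only that the choice between these scalings accounts for little of the rise. The trend with gene span was small too, -0.098 at the 10th and -0.314 at the 90th percentile of span. The median was 2.21 (quartiles 0.48 and 2.88) once that trend was removed for all 21 members, so gene span accounts for little of the rise. A low level in the Halr1-WT control cannot be told apart, because the median against Hoxa1-WT, 0.69, lay between the limits of 0.5 and 1 set for that test. A share of endoderm cells in the knockout culture or a difference between clones may also account for it, and neither was tested.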

How the results depend on the processing

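Chosen after the data were seen were scaling by library totals alone and Hoxa1-WT as control for Halr1-KO; the other alternatives were planned. Of 731 named gene results, 731 kept direction and call with RLE scaling, 709 with DESeq2 (20 weaker, 2 stronger) and 726 without a filter. With library totals alone 716 kept them, and Tbx3 in En1/2/3-KO turned to -0.048. In fits of the compared groups alone 719 kept them, 2 were weaker, 3 were stronger and the rest were not tested. Of 280 list results 213 kept their call with an estimated correlation and 67 were weaker; with RLE scaling 279 kept it, and the neural list in En1-KO was weaker (median 0.49, adjusted p = 0.0509). Keeping merged libraries apart was not run, since none was merged. What depth limits was not simulated by expression level; genes of a few CPM rest on few counts.

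Requiring a change of 1 on the log2 scale left, by construction, 7582 genes for RA, 3897 for Halr1-KO, 1478 for Hoxa1-KO, 1262 for DKO, 1902 for DKO minus Hoxa1-KO, 7162 for DKO minus Halr1-KO, 4336 for the difference of the Halr1-KO and Hoxa1-KO effects, 4358 for Halr1 loss with and without the Hoxa1 knockout, 3811 between wild types, 2467 for En1-KO, 787 for En2-KO, 988 for En1/2/3-KO, 1775 against En1-KO and 118 against En2-KO. Halr1-KO gave 11850 genes against Hoxa1-WT and 11202 against both wild types, and RA 13157 with Halr1-WT alone and 11802 with Hoxa1-WT alone. DKO gave 10405 genes against Halr1-WT and 8344 against both wild types. DESeq2 gave 3491 genes for En2-KO and 950 for En1/2/3-KO minus En2-KO; the cause was not tested.

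Leaving out each library in turn, which leaves 1 sample in an enhancer group and assumes that it varies like the others, gave 12419 to 12915 genes for RA, 8851 to 9287 for Halr1-KO, 5373 to 5846 for Hoxa1-KO, 4355 to 4568 for DKO, 6072 to 6327 for DKO minus Hoxa1-KO, 11475 to 11731 for DKO minus Halr1-KO, 8070 to 8544 for the difference of effects, 8012 to 8535 for Halr1 loss with and without the Hoxa1 knockout and 9148 to 9457 between wild types. It gave 6863 to 7438 for En1-KO, 3578 to 4224 for En2-KO, 4795 to 5400 for En1/2/3-KO, 4958 to 5311 against En1-KO and 787 to 1061 against En2-KO (787 without En1/2/3-KO replicate 1, 845 without its replicate 2, 1004 and 1061 without En2-KO replicate 1 and 2). Fewer libraries were fitted in each.

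With the replicate number as a replicate block the counts were 12934 for RA, 9497 for Halr1-KO, 6345 for Hoxa1-KO, 5380 for DKO, 6892 and 11956 for DKO minus Hoxa1-KO and minus Halr1-KO, 8500 and 8477 for the differences, 9867 between wild types, 8511 for En1-KO, 5155 for En2-KO, 6517 for En1/2/3-KO, 6399 against En1-KO and 1659 against En2-KO. The labels share only a number: same-numbered libraries had correlations of -0.104 to 0.133, so they were not taken as pairs.

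With an estimated correlation the lists past the threshold fell from 7 to 1 for RA, 9 to 3 for Hoxa1-KO, 6 to 3 for DKO, 8 to 2 for En1-KO, 8 to 0 for En2-KO and 6 to 0 for En1/2/3-KO, and stayed at 5 for Halr1-KO. RA-responsive medians of 0.33 and -0.49 in Halr1-KO (adjusted p = 0.105 and 0.0843), 0.16 and -0.30 in Hoxa1-KO (0.386 and 0.105) and -0.052 in DKO (0.607) no longer passed, nor did the DKO median of -0.048 with lists of 500 genes (adjusted p = 0.149); with lists of 100 it was -0.18 and passed (adjusted p = 0.00142). Overlap of opposite calls had odds ratios of 1 and 1.01 among genes of at least 5 CPM. The cause was not tested.

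Direction turned for the following genes. In Halr1-KO against both wild types: Zscan4a -0.30, Gata3 0.065, Ccnd1 0.028 and mt-Nd2 -0.054. In Halr1-KO against Hoxa1-WT: Hoxa1 -0.76, Hoxa9 -0.14, Magea8 0.73, Magea5 0.18, AC141438.1 1.12, Spry2 -1.02, Esx1 0.18, Lamb1 -0.085, Hoxc13 0.83, Zscan4a -2.12, Cyp26a1 -0.59, Gata3 1.49, Hoxb4 -0.45, Dnmt3a -0.33, Ccne1 -0.018, Dusp6 -0.61, Pdgfrb -0.094, mt-Nd5 -0.10, Ei24 0.049, Dnajb1 0.16, Ccnd1 0.52 and mt-Nd2 -0.49. In Hoxa1-KO against both: Hoxa5 0.15, Hoxa7 0.21, Hoxa4 0.95, Lamb1 0.32, Dnmt3a 0.12, Ccne1 0.054 and Pcna 0.34. In DKO against Halr1-WT: Hoxa7 0.64, Hoxa5 1.04, Hoxa3 1.39, Rnf181 0.51, Plagl1 -2.35, Scml2 -1.93, Rhox13 -1.25, Hotairm1 0.93, Wnt3a 1.21, Hoxb6 0.69, Hoxb5 0.31, Hoxb8 1.32, Axin2 0.44, Klf4 0.063, Esx1 -1.39, Spry2 2.56, Ccne1 0.26, Myc 0.14, Hoxb2 1.29, Dnmt3a 0.90, Cdx1 0.41 and Pim1 0.16. In DKO against both: Hoxa5 0.11, Hoxa3 0.50, Hoxb8 0.21, Esx1 -0.28, Spry2 0.91, Hoxb2 0.34, Dnmt3a 0.16 and Cdx1 0.013. The control libraries of these settings differ, as the levels of the wild types show.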

Other observations

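The values below were chosen after the data were seen, apart from the rise of Uqcrc1 in Halr1-KO, which the rule for named genes takes.

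Trp53 itself varied in the first arm, where neither targeted gene lies on its chromosome. It stood at 341 CPM in WT-RA-0d, 385 in Hoxa1-WT and 360 in DKO, but at 139 in Halr1-WT, 193 in Halr1-KO and 104 in Hoxa1-KO.

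Hoxc genes had counts in some wild types and not in others. Hoxc12 had no count in Hoxa1-WT and 2.23 CPM in Halr1-WT. That is 22.1-fold the floor of 3 counts over the group, a lower bound of the difference. Hoxc11 was at 0.838 CPM in Halr1-WT and 1.29 CPM in Hoxa1-KO with no count in Hoxa1-WT.

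Uqcrc1 and Ppp1ca had uneven counts within groups. Uqcrc1, a gene of the respiratory chain, passed in Halr1-KO (log2 fold change 4.61 ± 1.38, edgeR adjusted p = 0.00562) with between 49 and 2854 counts in the 3 libraries of that group (178 ± 227 CPM). It had 41 to 2547 in Hoxa1-WT and 37 to 2245 in DKO. Ppp1ca had 44 to 1011 counts in Hoxa1-WT and 84 to 1245 in Hoxa1-KO.

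Mitochondrial transcripts took 0.557% of the gene counts in Halr1-KO and 0.767% in Halr1-WT, against 1.46% to 3.84% in the other groups, and the 100 most abundant genes took 31.1% and 26.2% against 17.5% to 21.1%.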
